A study of Danio rerio with 4 samples.

How the data were processed

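RNA was measured in GFP-positive cells sorted from zebrafish (Danio rerio) embryos 3 days after fertilization. Per the labels' protocols, a block of tissue containing the kidney was cut from embryos of a line in which the cmyb (myb) promoter drives EGFP, digested with 0.25% trypsin for 1 hour, passed through a 40 µm strainer and sorted, and 20000 GFP-positive cells were taken for RNA extraction. The labels call the sorted cells kidney multiciliated cells. From each extract, 100 ng of total RNA was amplified with an Ovation kit, labelled with biotin and hybridised to an Affymetrix zebrafish array. There were 2 arrays from embryos injected with a control morpholino and 2 from embryos injected with a morpholino against miR-34b, and the series design describes the replicates as 2 independent biological sets.

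The values deposited by the authors are log2 signals per probe set. MAS5 is named in the submitters' processing notes, with no version, and the mean signal after trimming 2% at each end was 500.1 on each of the 4 arrays, so the deposited log2 values had been scaled to a common level per array. The lowest value on each array was 0, and between 118 and 189 of the 15617 probe sets lay there. Detection calls were not used here. The medians of the arrays were 7.18 and 7.19 in the controls and 7.29 and 7.22 in the morphants. On arrays the number of samples limits the precision, and with 2 against 2 an exact two-sided permutation test cannot go below p = 0.333.

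Group differences were fitted with limma 3.58.1 in R 4.3.3, with 1 term for the group and moderated variances (no trend, not robust), and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Positive values are higher in the morphants. The plan had been to add a pseudocount of 16 to linear signals. The values turned out to be on a log2 scale already, so none was added, and 16 became an alternative. The 115 control probe sets were left out, as were the lowest 25% of the others by mean over the 4 arrays, which left 11626 probe sets. As the annotation on hand pairs probe sets with genes, 10795 probe sets had 1 gene symbol, 135 had several and were given no name, and 4572 had none. Symbols were updated through the Entrez gene numbers of a RefSeq gene table for assembly GRCz12tu: 10711 probe sets matched and 1 symbol changed. The build behind the array is not given in the sources used here, so the table served only for names and for the order of neighbouring genes, and no positions are printed.

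A total of 21 gene lists, 12 of pathways and 9 of cell type markers, were fixed before the data were examined. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene (the brightest), against all other named genes tested, with Benjamini-Hochberg adjustment over the 21 lists. Camera with an estimated correlation and fry were run beside it. The genes named in the report follow a rule fixed at the same time. It takes the 15 higher and 15 lower genes with the largest changes among probe sets past the threshold whose groups do not overlap, filling empty places with genes of smallest p and at least 2-fold difference that did not pass. It also takes the 2 to 4 genes per list with the strongest statistic, up to 4 of the brightest genes of each marker list, and a short list of regulators. Of that last list, foxj1a, foxj1b, gmnc, ccno, ccp110 and cdkn1a have no probe set in the annotation used here. The text gives part of the genes this rule takes, and 1 of the 21 lists is not reported here. A probe set whose signal in a group lay within the range of control probe sets for sequences absent from zebrafish has only a bound in that group, computed against the higher of its own signal and the brightest such control on each array.

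The fit was tested on simulated arrays with the spread of the real ones, 20 times, with 200 of the 11626 probe sets changed each time. It recovered 59.9% of changes of 2 on the log2 scale and 0.748% of changes of 1. Of the calls, 1.37% were unchanged probe sets, and 0 probe sets were called on average where nothing was changed. Errors were drawn independently for each probe set, with no effect shared over an array. On the real arrays 2057 probe sets had unadjusted p under 0.05, and the adjusted threshold is less strict when more probe sets differ. The simulated shares therefore need not hold for the real arrays. The share of false calls depends on the simulated spread: a first version that drew already moderated variances gave a higher share and was replaced by draws from the fitted variance distribution. Camera gave p under 0.05 to 2.38% of lists in unchanged data with independent genes, and called a list of 40 genes raised by 1 in 100% of simulations. Alternatives covered the pseudocount, the filter, quantile, median and cyclic loess scaling, the variance prior, unmoderated p-values, array weights, the replicate number as a block, each array left out, and other list tests. A planned test of genes carrying a miR-34b seed site in the 3′ UTR needs transcript sequences and was not analysed here.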

Results

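Expression was compared between GFP-positive kidney cells of 3-day zebrafish embryos that had received a control morpholino (n = 2 arrays) and cells of embryos that had received a morpholino against the microRNA miR-34b (n = 2 arrays, called morphants here). Morpholinos are antisense oligomers that block splicing, translation or processing of an RNA. The comparison asks which transcripts differ when miR-34b is targeted, in sorted cells that the labels call multiciliated cells, which carry many motile cilia. Transcripts used as markers of other cells were bright in them too. The myeloid and leukocyte list had the highest median level of the gene lists, 11.49 (log2, mean over arrays) against 9.35 for axoneme genes. Of its 33 genes, 10 stand in another list too. The share of multiciliated cells among the sorted cells was not measured. The annotation names 0 probe sets for the miR-34 genes, so the targeted RNA itself could not be followed. The control arrays correlated at r = 0.981 across the probe sets tested and the morphant arrays at r = 0.977, against 0.956 to 0.958 between groups; probe sets are not independent replicates. The poly-A spike-in controls, added before amplification, averaged 9.95 and 9.96 (log2) on the control arrays and 9.54 and 8.73 on the morphant arrays. The 3′ minus 5′ signal of the controls for acta1, an actin of skeletal muscle, was highest on morphant replicate 2, at 3.39 against 2.38 to 2.54 on the others. The GAPDH 3′ minus 5′ signal did not set that array apart, at 1.02 and 0.88 on the control arrays and 0.36 and 0.94 on the morphant arrays.

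Genes of motile cilia were higher in the morphants, and most of the differences that passed the test went that way, while probe sets with separate groups split about evenly. In limma's test, 290 probe sets were higher and 14 lower (Benjamini-Hochberg adjusted p under 0.05; 206 and 11 named genes). Of the 206 named genes, 67 belonged to the 4 lists of cilium genes and 132 to no list. Over the 2 groups of arrays, 537 probe sets were separate and at least 2-fold higher and 160 at least 2-fold lower. The other 2 ways of pairing the arrays gave 27 and 39 and 62 and 18. A probe set without ties is separate in only 1 of the pairings, and the other pairings hold the real group difference as spread. Their counts are therefore no independent measure of chance. Some 49.8% of probe sets had separate groups, where chance gives 33.3%, and these were 2920 higher and 2873 lower. At unadjusted p under 0.05, 1348 were higher and 709 lower, and 1131 and 994 after median centring. The median log2 fold change of all probe sets tested was −0.017. The number of calls rested on the arrays and the filter. Without control replicate 1 limma called 47 higher and 7 lower, and without control replicate 2 it called 53 and 1. Without morphant replicate 1 it called 0 (1089 higher and 828 lower at unadjusted p under 0.05), without morphant replicate 2, the array with the dimmest poly-A controls, 0 (1276 and 727), and without the filter on dim probe sets 0 (1380 and 647). Every per-gene call named below was lost without either morphant array and without the filter.

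**Figure D1:**
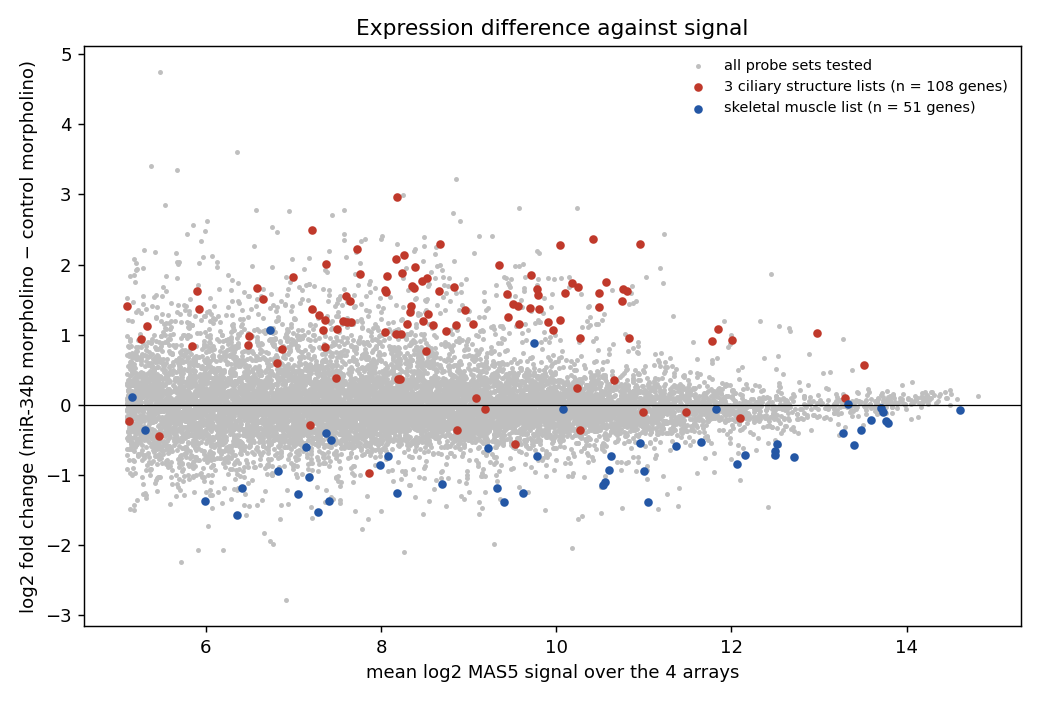
Each point is a probe set, with its mean log2 MAS5 signal over the 4 arrays on the x axis and the log2 fold change, morphants minus controls, on the y axis. Grey points are all 11626 probe sets tested, red points are the 108 genes of the 3 ciliary structure lists (median 1.26) and blue points the 51 genes of the skeletal muscle list (median −0.72).

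The structural genes of the motile cilium rose as a group. Of 55 axoneme, dynein arm and assembly genes tested, 35 rose, 0 fell and 20 did not pass. Adjusted over the list alone, 48 were higher and 1 was lower. Their median log2 fold change was 1.37, or 2.58-fold. Genes that rose included cimip2b, a protein inside ciliary microtubules (2.97 ± 0.18, SE), tekt1, a tektin of the axonemal doublets (2.30 ± 0.17), efhc2, another axonemal microtubule protein (2.27 ± 0.16), and dynlt5, a dynein light chain (2.13 ± 0.16), each with an adjusted p of 0.0153. Intraflagellar transport and Bardet-Biedl genes, which carry cargo along the cilium, had 13 of 24 higher, 0 lower and a median of 1.17 (20 and 0 adjusted over the list alone). Among them were cluap1 (2.23 ± 0.16), bbs7 (1.87 ± 0.17), arl6 (1.82 ± 0.17) and dync2i2 (1.70 ± 0.16). Genes of the transition zone, centriole and basal body had 13 of 29 higher, 0 lower and a median of 1.08 (21 and 0 adjusted over the list alone). They included the centriole duplication gene stil (2.50 ± 0.18), and mks1 (1.62 ± 0.16) and tmem67 (1.68 ± 0.17) of the transition zone. Taking these 3 lists together, 61 of 108 genes rose and 96 had both morphant arrays above both control arrays. Camera gave the lists adjusted p-values of 1.66e-34, 3.76e-17 and 3.50e-13. With an estimated correlation the adjusted p was 0.258 for each, and fry gave 0.0128, 0.0135 and 0.0128.

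Regulators of ciliogenesis and multiciliation were also higher. Of 20 tested, 6 rose, 0 fell and the median was 0.73, or 0.42 with the lowest 50% of probe sets left out (10 and 0 adjusted over the list alone; camera adjusted p = 9.32e-05, adjusted p = 0.258 with an estimated correlation, fry 0.0135). The forkhead factor foxn4, which acts in multiciliated cells, rose by 3.22 ± 0.21 (SE, adjusted p = 0.0153), and its other probe sets gave 2.71 and 1.85, the latter with 1 of the 2 control arrays at background, within the range of controls for absent sequences. The cell cycle factor e2f5, a partner of the multiciliation coactivators, rose by 2.26 ± 0.28 (adjusted p = 0.0283; a second probe set gave 2.08, with 1 control array at background), and the ciliary factor rfx2 by 1.49 ± 0.19 (adjusted p = 0.0290), though a second rfx2 probe set gave 0.31. The myb family member mybl1 rose by 1.25 ± 0.17. The transcript of myb, whose promoter drove the reporter used for the sort, did not pass, at −0.42 ± 0.19 (adjusted p = 0.349).

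**Figure D2:**
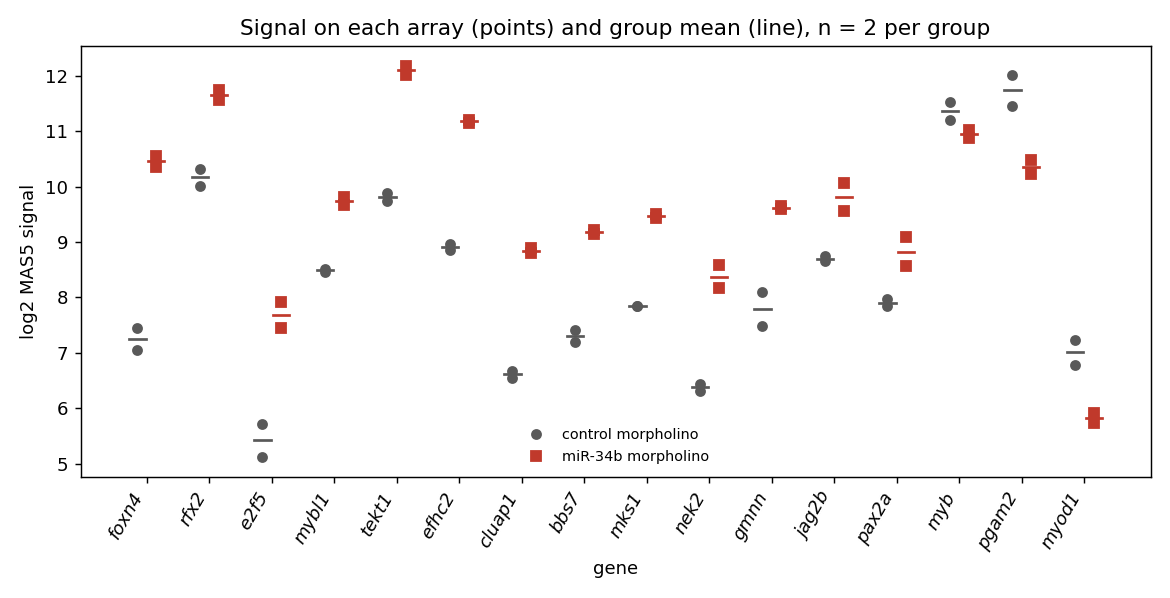
Points give the log2 MAS5 signal of named genes on each array and lines the group means (n = 2 per group), grey for the control morpholino and red for the miR-34b morpholino. Both morphant points of foxn4 lie near 10.46 on average against 7.24 in the controls, while pgam2 and myod1 of the muscle list lie lower in the morphants.

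Notch pathway genes, which set how many precursors become multiciliated, gave no call. In this list 0 of 28 passed in either direction and the median was 0.015 (0 adjusted over the list alone; camera adjusted p = 0.482). The ligand jag2b was 1.11 ± 0.22 higher (adjusted p = 0.0801), her2 1.51 ± 0.42 higher and nrarpb −0.54 ± 0.17. Without morphant replicate 2 the Notch median was 0.32 and camera's adjusted p 0.0308. The list of miR-34 family targets described in other systems had 2 of 38 higher, 0 lower, and a median of −0.079 (3 and 0 adjusted over the list alone; camera adjusted p = 0.846). The 2 were e2f5 and gmnn, geminin, an inhibitor of replication licensing and of multicilin (1.83 ± 0.25, adjusted p = 0.0320). The receptor met had 1.22 ± 0.21 (adjusted p = 0.0579) and ldha −0.61 ± 0.19. Genes of basal body docking, actin and planar polarity had 0 of 32 past the threshold (0 adjusted over the list alone) and a median of −0.080 (camera adjusted p = 0.404).

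Genes of the kidney tubule and of the cell cycle were close to 0 as groups. Of 36 pronephric tubule and podocyte genes, 2 rose and 0 fell (6 and 1 adjusted over the list alone; median −0.022, camera adjusted p = 0.482). They were the chloride channel clcnk (1.55 ± 0.21, adjusted p = 0.0320) and agxta, an aminotransferase (1.41 ± 0.22, adjusted p = 0.0475). pax2a had 0.92 ± 0.23 (adjusted p = 0.130). Of 76 cell cycle and DNA replication genes, e2f7, a repressor E2F factor, rose by 2.11 ± 0.16 (adjusted p = 0.0153) together with gmnn, and 0 fell (2 and 0 adjusted over the list alone). The median was −0.080 (camera adjusted p = 0.237), and without morphant replicate 2 it was −0.16 with camera's adjusted p at 0.0154. Dissociation stress and heat shock genes had 1 of 54 lower, the small heat shock gene hspb8 (−1.10 ± 0.17, adjusted p = 0.0475), and a median of −0.14 (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0466, adjusted p = 0.637 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.119) and without morphant replicate 2 (median −0.081, adjusted p = 0.495). The cytosolic chaperones hsp90aa1.1 (−2.04 ± 0.36, adjusted p = 0.0607) and hsp90aa1.2 (1.19 ± 0.20, adjusted p = 0.0569) pointed in opposite directions. A second hsp90aa1.2 probe set gave 1.45 (adjusted p = 0.118). The signal of hsp90aa1.1 was 11.67 and 10.71 on the control arrays and 9.35 and 8.96 on the morphant arrays, the array order of the muscle list's mean. The paralogs are close in sequence, so the sizes of these values are uncertain. The interferon and inflammation list had 0 of 30 past the threshold (0 adjusted over the list alone; median −0.13, camera adjusted p = 0.0629), and passed without control replicate 1 (adjusted p = 0.0344).

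**Figure D3:**
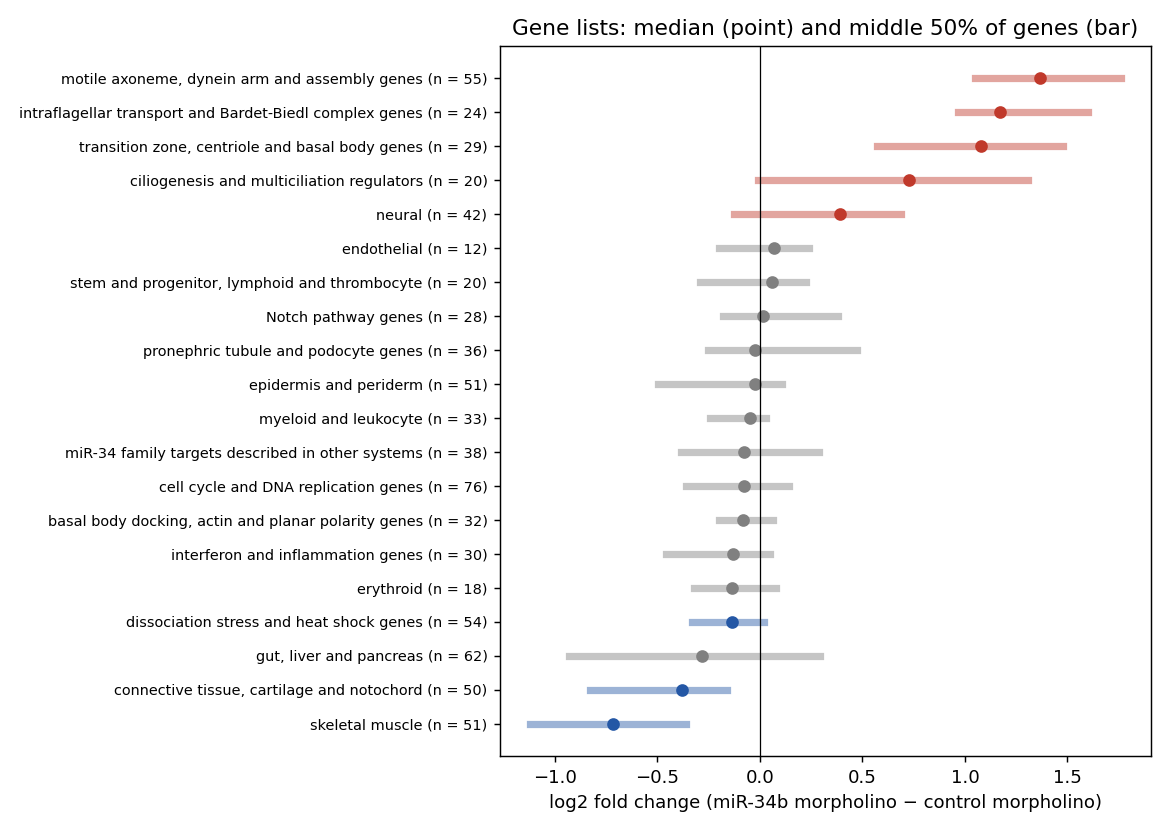
Points mark the median log2 fold change, morphants minus controls, of each gene list reported, and bars the middle 50% of its genes, with the number of genes tested in parentheses. Lists in red or blue passed camera's threshold at the preset correlation, higher or lower in the morphants; the 3 ciliary structure lists lie highest, with medians from 1.08 to 1.37.

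Markers of other cells that the tissue block holds moved differently from each other. Skeletal muscle genes were lower, with a median of −0.72 over 51 genes, and 0 passed the test over all genes (1 higher and 9 lower adjusted over the list alone). The members with the strongest statistic were pgam2 (−1.39 ± 0.24, adjusted p = 0.0618), myod1 (−1.19 ± 0.22, adjusted p = 0.0647), ldb3a (−1.26 ± 0.24, adjusted p = 0.0744) and nexn (−1.53 ± 0.30, adjusted p = 0.0757), none of which passed. The values of the brightest members were smaller, with actc1b at −0.071 ± 0.23, tnnc2.2 at −0.27 ± 0.22, tnni2a.4 at −0.23 ± 0.23 and pvalb2 at −0.10 ± 0.18. Camera gave adjusted p = 4.43e-10, and adjusted p = 0.637 with an estimated correlation. The list's mean differed by 0.26 and −0.26 from the control mean on the control arrays and by −0.43 and −0.90 on the morphant arrays. Without control replicate 1 its median was −0.44 and without morphant replicate 2 it was −0.38. Connective tissue, cartilage and notochord genes had a median of −0.38 over 50 genes with 0 past the threshold (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 2.70e-05, adjusted p = 0.442 with an estimated correlation). Among them, and2 had −1.51 ± 0.27, and3 −1.98 ± 0.40 and col1a1a −0.94 ± 0.18, while sox9b had 0.91 ± 0.17. Without morphant replicate 2 that median was −0.14, and with a pseudocount of 64 it was −0.25. Neural genes had a median of 0.39 over 42 genes with 0 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.0110, adjusted p = 0.637 with an estimated correlation), and 29 were above 0 and 13 below. The strongest statistics were those of stmn2a (1.15 ± 0.22), snap25a (0.71 ± 0.18), elavl3 (0.98 ± 0.27) and snap25b (0.70 ± 0.20). Of the brightest members, fabp3 (−0.23 ± 0.17), rtn1a (−0.34 ± 0.20) and fabp7a (−0.50 ± 0.63) lay below 0 and cplx2a (0.26 ± 0.16) above. The neural call was lost without control replicate 2 (0.35, adjusted p = 0.129) and without morphant replicate 1 (0.35, adjusted p = 0.0621), and the median was 0.25 with a pseudocount of 64.

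Blood, vessel and epithelial markers gave no list call. The erythroid list had 0 of 18 past the threshold (median −0.14, camera adjusted p = 0.230), with hbae3 at −0.14 ± 0.32, and passed without control replicate 2 (adjusted p = 0.0183). Of the 18 erythroid genes, 13 lay below 0 and 5 above. Among them tmod4 had −1.59 ± 0.35, hbbe2 −1.06 ± 0.64, cahz −0.75 ± 0.27 and slc25a38b 0.37 ± 0.16, none of which passed. The log2 signal of tmod4 was 11.49 and 10.68 on the control arrays and 9.81 and 9.18 on the morphant arrays. That is the array order of the muscle list's mean, so its value cannot be read as one of blood cells alone. The myeloid and leukocyte list had 0 of 33 (median −0.049, camera adjusted p = 0.195). Its bright genes lyz (0.010 ± 0.17), cpa5 (−0.027 ± 0.17) and mmp13a (0.036 ± 0.17) lay near 0, and the values of lyz and mmp13a turned negative under quantile and median scaling. Their mean log2 signals were 14.04, 14.17 and 13.80 in the controls and 14.05, 14.15 and 13.84 in the morphants, and cpa5 stands in the gut list too. The stem, progenitor, lymphoid and thrombocyte list had 0 of 20 (median 0.059) and the endothelial list 0 of 12 (median 0.067), each with a camera adjusted p of 0.846. Epidermal and periderm genes had a median of −0.025 over 51 genes (camera adjusted p = 0.482), which was −0.19 without control replicate 1, −0.097 without control replicate 2 and −0.10 without morphant replicate 1 (adjusted p = 0.0683). In this list the desmosomal gene pkp3a (1.11 ± 0.16, adjusted p = 0.0374) and the fatty acid elongase elovl7a (1.22 ± 0.19, adjusted p = 0.0462) rose. Adjusted over the lists alone, the counts were 0 in the erythroid, myeloid, stem and endothelial lists, and 5 higher and 2 lower in the epidermal list. Gut, liver and pancreas genes had a median of −0.28 over 62 genes (1 higher and 0 lower, also when adjusted over the list alone; camera adjusted p = 0.0901). The carboxypeptidase cpb1 rose by 1.92 ± 0.16 (adjusted p = 0.0183), and a second probe set gave 1.43 ± 0.38 and did not pass (adjusted p = 0.148). The elastase ela2 had −2.78 ± 0.50 (adjusted p = 0.0647) and the insulin gene ins 2.46 ± 0.55 (adjusted p = 0.104). Its control arrays spread most among the lists (SD 0.53), and its median ran from −0.61 without control replicate 1 (adjusted p = 7.40e-08) to 0.0038 without control replicate 2, with −0.34 (adjusted p = 0.0143) without morphant replicate 1.

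Outside the cilium lists, the largest rises among named genes that passed were those of ehf, an epithelial ETS factor (3.60 ± 0.27, SE), and elavl2, an RNA-binding protein (adjusted p = 0.0427). In elavl2 both control arrays lay within the range of the absent-sequence controls, so the difference is at least 6.75-fold. For ehf, btg4 and ncs1b this held on 1 of the 2 control arrays. cnn3b, a calponin, rose by 3.00 ± 0.22, btg4, an adaptor of the CCR4-NOT complex, by 2.84 ± 0.20, and nudt9, an ADP-ribose pyrophosphatase, by 2.81 ± 0.18 (second probe set 2.43). Others were s100b (2.80 ± 0.21), pias4b (2.78 ± 0.37), hoxb5a (2.78 ± 0.19), ncs1b (2.62 ± 0.22) and tsga10 (2.62 ± 0.19). The synaptonemal gene sycp1 rose by 2.76 ± 0.24 in 1 probe set and gave 0.74 in the other. Among the 11 named genes that fell were ftr86 (−1.63 ± 0.26, adjusted p = 0.0497), rcn3, a calcium-binding protein of the secretory pathway (−1.61 ± 0.24, adjusted p = 0.0408), the cobalamin-binding tcnbb (−1.47 ± 0.20, adjusted p = 0.0320), and bzw2 (−1.39 ± 0.16, adjusted p = 0.0233). The receptor gpr132b (−1.29 ± 0.19), fkbp9, a prolyl isomerase of the endoplasmic reticulum (−1.17 ± 0.18), zdhhc5b (−1.13 ± 0.17) and col15a1b, a basement membrane collagen (−1.04 ± 0.16), fell as well. aqp3a, a water channel, had −1.08 ± 0.19 and did not pass (adjusted p = 0.0607).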

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

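The test in this part was chosen after the values were seen. A control probe set on the array, left out of the group tests and given no name by the annotation used here (AFFX-Dr-U43284-1_s_at), was brighter in the morphants. Its log2 signal was 12.38 and 12.20 on the control arrays and 13.90 and 13.72 on the morphant arrays, a difference of 1.52. Like all 115 control probe sets, it is left out of the report's comparisons.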

How the results depend on the processing

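The pseudocount of 16 was added after seeing the data, and the other settings were fixed before. The counts moved more than the directions. Higher calls (290) became 495 with a pseudocount of 64, 508 with a trended and robust prior, and 0 with no filter or with unmoderated p-values. Lower calls (14) became 81 with a pseudocount of 64, 34 with 16, 63 with the lowest 50% left out, 8 with quantile normalization, 7 with cyclic loess, 101 with the trended prior, and 0 with no filter or unmoderated p-values. Unmoderated p-values gave 935 higher and 494 lower at unadjusted p under 0.05. With no filter, limma's prior degrees of freedom fell from 3.28 to 1.82 and the lowest adjusted p was 0.113, against 0.0153. Separate and at least 2-fold counts (537 and 160) became 276 and 51 with a pseudocount of 64, 933 and 426 with no filter and 327 and 82 with the stricter filter, and the lower one 97 with a pseudocount of 16. Leaving out each array in turn gave 0 to 53 higher and 0 to 7 lower calls, and 555 to 665 and 174 to 340 separate ones. That removes 1 of 4 samples, and the lone array of a group is assumed to vary like the other group. Groups are separate by chance more often with 1 array against 2 than with 2 against 2. The 555 to 665 and 174 to 340 therefore cannot be compared with 537 and 160.

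The 4 cilium lists and the muscle and connective lists kept camera's call under every camera setting run except the estimated correlation. There the medians stay (1.37, 1.17, 1.08, 0.73, −0.72 and −0.38) and the test widens. The estimated correlations of the cilium lists were 0.10, 0.17, 0.028 and −0.034, against the preset 0.01. For the regulators the estimate lay below the preset, so a higher correlation does not account for that lost call. With fry the cilium lists kept their call, but muscle, connective (adjusted p = 0.386 and 0.245), stress and neural did not. The neural call was lost with no filter (0.31) and with either of the 2 other list tests (0.39), and its median ran from 0.34 to 0.46 with 1 array left out and was 0.25 with a pseudocount of 64. The stress call was lost with no filter (−0.13), quantile (−0.15), median (−0.21) and loess (−0.12) scaling, the 2 other list tests and the mean of all probe sets (−0.14), and ran from −0.22 to −0.081 with 1 array left out. Unless the construction shows it, the cause was not tested. The gut list also passed with a pseudocount of 64, the stricter filter, the trended prior and the block. No called value changed sign under these alternatives. The small medians of the Notch, miR-34 target, pronephric, cell cycle, stem and endothelial lists did with some array left out. The Notch, stem and endothelial medians also turned sign under some other scaling. With another filter, the pronephric, cell cycle, stem and endothelial medians turned sign. Of the alternatives for single named genes, 1663 left the call as it was, 230 ended it, 98 added one, and 23 turned the sign of an uncalled value. Whether equal replicate numbers mark a shared set is not given, and replicate 1 minus 2 correlated at 0.021 between groups across probe sets, so the arrays were taken as unpaired; with the replicate block 196 higher and 11 lower were called, and 184 of the 290 and 4 of the 14 were among them. Between arrays of the same number the muscle list's mean differed by −0.69 and −0.64. The seed-site settings were not run, since transcript sequences were not used here. The brightest absent-sequence control lay at 3.71 to 4.93 (log2), and 76.9% to 87.5% of probe sets lay above it on an array, so differences of dim probe sets are less certain.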

Other observations

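All tests in this part were chosen after the values were seen, apart from that of the 3 other scalings. The higher calls reached beyond cilium genes. A list of 36 germ cell genes, written after 7 of them had been noticed among the largest differences, had 14 genes tested on their brightest probe set and 5 past limma's threshold; sycp1 gave 0.74 there and passed only in its dimmer probe set. They were elavl2, nanos3 (2.02 ± 0.30, SE, adjusted p = 0.0389), tdrd6a (1.93 ± 0.23), tbpl1, a TBP-related factor (1.60 ± 0.16), and the egg coat gene zp3d.2 (1.26 ± 0.18). ddx4, the germ line helicase vasa, had 4.74 ± 0.82 and did not pass (adjusted p = 0.0580), with controls at 1.81 and 4.40 and morphants at 7.97 and 7.72. In ddx4, nanos3 and tdrd6a 1 of the 2 control arrays lay within the range of the absent-sequence controls, and in elavl2 both did, so the sizes of these differences are uncertain. The 7 listed genes that had not been noticed had a median of −0.076, 3 of 7 were above 0 and 0 passed, against a median of 0.62 and 10 of 14 above 0 over all the listed genes tested. The list was not tested as a set, since 7 of its genes were picked for their values.

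The rise of the ciliary genes was weighed against technical explanations. For scaling between arrays, the lowest median of the 3 ciliary lists under quantile, median and loess scaling was 1.19 against 1.26 (bootstrap range over genes 1.15 to 1.41). Each scaling aligns the bulk of probe sets, whose median difference was already −0.017, so this outcome was nearly fixed in advance. It shows that the ciliary genes rose relative to the other probe sets, and does not test the scaling itself. That morphant replicate 2, the array with the dimmest poly-A controls, alone made the rise is argued against, since the median without it was 1.27. Morphant replicate 1 also had dimmer poly-A controls than the control arrays (9.54 against 9.95 and 9.96). Leaving out 1 array therefore cannot test poly-A controls that are dimmer in the whole group. A larger share of multiciliated cells among the sorted cells may account for it as well as more transcript per cell from miR-34b knockdown, and these cannot be told apart. The log2 fold changes of the ciliary genes varied 3.50 times as much as their standard errors, but expression in other cells and compression of bright signals would also spread them.

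The lower muscle list was weighed in the same way; the sort on GFP was meant to remove such cells, and 1 of its 51 genes stands in another list. Less carry-over of every other tissue would lower the neural and epidermal lists too. The neural mean minus the muscle mean, taken per array, was 0.95 ± 0.28 (SE over arrays) higher in the morphants. The epidermal mean minus the muscle mean was 0.55 ± 0.27 higher. With 2 arrays per group these standard errors are themselves uncertain, so a cutoff of 2 standard errors does not decide it. Dilution by more ciliated-cell RNA would lower neural and myeloid genes alike. The same 0.95 bears on it, but the myeloid list gave 0.59 ± 0.37, within 2 standard errors. Between arrays of the same replicate number, neural minus muscle was 0.92 and 0.97 and myeloid minus muscle 0.51 and 0.68. The muscle mean itself differed by −0.69 and −0.64. These values lie closer together than the unpaired standard errors convey, which would matter if equal numbers marked a shared set. Like muscle, the connective (median −0.38), gut (−0.28) and erythroid (−0.14) lists lay below 0. In the erythroid list, tmod4 followed the array order of the muscle mean, so that list is not cleanly separate from muscle. The neural (0.39), endothelial (0.067) and stem (0.059) lists lay above, and the epidermal (−0.025) and myeloid (−0.049) lists near it. The neural call was lost under several settings, so both explanations stay open. A first test that relabelled genes gave permutation p = 1e-05, the smallest it can give, for neural and for myeloid against muscle, and was replaced by the spread over arrays because the muscle genes move together (estimated correlation 0.758). Muscle carry-over that varies between single arrays stays open and cannot be told apart from a group effect, because the muscle difference was 1.89 times its standard error over arrays taken as unpaired, and whether equal replicate numbers mark a shared set is not given; no biological explanation was tested.

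In the RefSeq order, btg4 is the array gene next to mir34b. It went from 4.32 and 3.90 to 6.97 and 6.94 (log2). The other 4 neighbours on the array had a median of −0.13, from ufc1 at −0.42 to hoatz at 0.74 ± 0.19 (adjusted p = 0.136), which argues against a rise of the whole neighbourhood. A larger share of multiciliated cells could account for btg4 too, and cannot be told apart from an effect at the locus. The size of the rise is uncertain, since 1 of the 2 control arrays lay within the range of the absent-sequence controls, so neither btg4 minus cimip2b, the ciliary gene that rose most (−0.12), nor its place above the bound first chosen, the upper end of the central 95% range of the ciliary genes (2.32), decides it.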
